A study of Drosophila melanogaster with 2 samples.

How the data were processed

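Chromatin immunoprecipitation with sequencing was analysed for 1 group of whole Drosophila melanogaster embryos, collected at 0 to 18 hours, in 2 biological replicates. The embryos came from a fly strain carrying the CkIIalpha-i1 protein fused to enhanced green fluorescent protein, and the immunoprecipitation used an antibody against that tag. Per the labels' protocols, chromatin was sheared by sonication to fragments of 200 to 800 bp. No other condition and no control library was analysed here, so nothing could be compared between conditions.

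The authors deposited 8 peak lists used here: for each replicate a ranked list and a thresholded list, and for the series 2 of each kind. Per the file headers and the deposited file records, coordinates are on the dm6 assembly and each list was made from alignments and a control file. The aligner and the peak caller are not given in the sources used here. In each ranked list, the deposited score of a peak is a scaled form of the irreproducible discovery rate (IDR, a measure of how well a peak's rank repeats between 2 input lists), and the signal value is the peak caller's own score, whose scale is not stated. The ranked lists also hold the deposited −log10 of the global IDR and the signal values of the 2 input peaks. All 4 thresholded lists held only peaks with a global IDR of 0.01 or less in their ranked list. The first input of the conservative list's ranked list held 86687 peaks identical in position and signal to peaks of replicate 1's own list, and its second held 86407 identical to those of replicate 2. The conservative list was therefore read as the comparison of the replicates. The other series-wide list is called the pooled list here; none of its inputs was identical to a replicate's peak. Because all signal values are the authors' scores per peak, they were used to describe, rank and filter peaks and to compare groups of peaks within a list. The exceptions are the correlations and log2 ratios between the replicates' signal values, which assume that both were scored alike. Read depth is unknown from these lists, so no depth-based interval is given.

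Peaks were analysed on the 6 main chromosome arms (2L, 2R, 3L, 3R, 4 and X). Their sequences and gene models came from the Release 6 reference and the Ensembl annotation BDGP6.54 (release 115). Every ranked peak on these arms lay within the reference arm lengths. Unless stated otherwise, the background was the peaks of the same ranked list that missed the IDR threshold, called failed candidates. Gene list members were compared with other genes, among protein-coding genes with any ranked peak at their promoter. Tests were Fisher's exact tests (two-sided) on peaks or genes, with Benjamini-Hochberg adjustment over the 7 annotation classes, 6 arms, 16 motifs or the gene lists. Medians were compared by two-sided permutation tests with 100000 resamples. Neighbouring peaks and genes are not independent replicates, so these p-values describe the lists and not the spread between embryo collections. The class of non-coding RNA exons was added to the planned 6. A promoter peak had its summit within 500 bp of an annotated transcription start site (TSS). Motifs and 7-mers were searched on both strands within 100 bp of the summit. The 7-mer search compared all peaks with failed promoter candidates on 2L and 3L, and the 20 best were tested again on the other arms. Replicate overlap of at least 1 bp was compared with 1000 random placements (one-sided).

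Before the data were examined, 24 gene lists, 16 motifs, the tests and the rule for named genes were fixed. The rule took the nearest gene of the 20 conservative peaks of highest signal that overlapped a thresholded peak of both replicates, the casein kinase II genes, and up to 4 members of each gene list by signal. Alternatives were the pooled list, each replicate's list alone, other TSS distances, motif windows, overlap rules and backgrounds. Added after the data were seen were IDR thresholds of 0.001 and 0.05, GC-matched backgrounds for the 7-mer search (from all failed candidates and from failed promoter candidates), and gene lists without the 65 conservative peaks of highest signal. The tests were tested on simulated sets of 653 peaks drawn from the conservative list's 136387 failed candidates. There, 2.0% of promoter tests, 1.30% of gene list tests and 5.31% of motif tests on unchanged sets had p under 0.05, all 5 planted 7-mers were recovered with 7 others, and the planted ribosomal list was called with 0 others. Drawn from failed candidates, the unchanged sets shared their GC content, while the real peaks had a lower one. These rates therefore do not cover the effect of that difference on the motif and 7-mer tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.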

Results

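Binding of CkIIalpha-i1, a protein named as an interactor of the alpha subunit of casein kinase II, was mapped in whole embryos of 0 to 18 hours through its green fluorescent protein tag. The data were the authors' peak lists for 2 biological replicates of 1 group. The thresholded lists held 427 peaks in replicate 1 and 569 in replicate 2. The conservative list, which compares the replicates, held 663 peaks, and the pooled list held 944. Of the conservative peaks, 653 lay on the main arms and 10 on unplaced contigs of the X chromosome.

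The replicates shared their strongest sites and differed at weaker ones. The highest peak in both replicates lay upstream of Ugalt, the gene of a UDP-galactose transporter. In all, 266 of the 427 replicate 1 peaks (62.3%) overlapped a replicate 2 peak, and 264 of the 569 replicate 2 peaks (46.4%) overlapped a replicate 1 peak. On the main arms 263 replicate 1 peaks overlapped, against a median of 1 and at most 6 in random placements (permutation p = 0.001, the smallest that 1000 placements can give). Among the 100 replicate 1 peaks of highest signal, 87 overlapped a replicate 2 peak, and 92 of the 100 highest of replicate 2 overlapped a replicate 1 peak. Only 265 conservative peaks (40.0%) overlapped a thresholded peak of both replicates. The self-consistency ratio, the larger replicate count over the smaller, was 1.33, and the rescue ratio, the larger series-wide count over the smaller, was 1.42. Across the 663 conservative peaks the 2 replicates' signal values had a Pearson r of 0.814 and a Spearman rho of 0.540. Across all 139481 candidates of that list r was 0.467 and rho was 0.201. These are correlations across peaks, which are not independent replicates. The conservative peaks were also selected by how well their ranks repeat between the replicates, so their higher correlation is partly set by that selection.

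**Figure D1:**
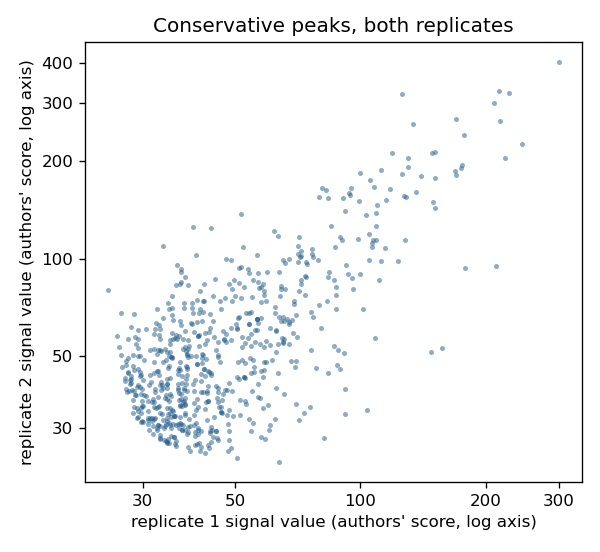
Each point is 1 of the 663 conservative peaks, with the authors' signal value in replicate 1 on the x axis and in replicate 2 on the y axis (both log axes). Spearman's rho across the peaks, which were selected by IDR, was 0.540, and the highest peak in both, at Ugalt, had 300.7 and 401.3.

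The 20 strongest shared sites (dm6, 1-based) lay mostly at promoters. The Ugalt peak at X 2703772 to 2703997 had a conservative signal value of 700.6 and its summit at −44 bp from the TSS (negative is upstream). CG14100 followed (3L 19590513 to 19590708, 547.1, −83 bp). Next came mRpL41, a protein of the large mitochondrial ribosomal subunit (2R 15217634 to 15217856, 541.2, −139 bp). The peak between CG7601 and CIA30 (3R 29736750 to 29736942) had a signal of 507.4. The peak at ph-p, a Polycomb group gene, lay inside the gene at −492 bp from its nearest TSS (X 2137247 to 2137462, 484.6). The peak between Tcs5, a kinase of tRNA modification, and CHMP2B, a membrane-scission factor, had 433.4 (3L 5139406 to 5139586). The peak at eIF6, a factor of large ribosomal subunit maturation, and the antisense gene asRNA:CR45928 had 426.5 (2R 23850315 to 23850493), and that at PNPase, the mitochondrial polynucleotide phosphorylase, had 422.6 (3R 31404560 to 31404738). Promoter peaks were also found between CenG1A and mRpS23 (367.9), between Art3 and mRpS10 (365.1), between CG5611 and Mtl (359.5), at CG18549 (352.2), at lncRNA:CR44619 (324.3), inside Chro, a chromodomain protein gene, near the facing Ssl1 (321.2) and at GstE13 (321.2). Those of the 20 outside promoters lay in introns of CG11050 (476.7, 1052 bp from the TSS), Adf1 (381.1, 772 bp) and CG32772 (357.5, 1258 bp), and between genes near CG13323 (364.6, 11954 bp) and lncRNA:CR45643 (321.4, −894 bp).

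Peaks were concentrated at promoters, just upstream of the TSS, and were scarce in coding sequence. On the main arms 357 of 653 conservative peaks were promoter peaks (54.7%, 95% Wilson interval 50.8 to 58.5), against 14.1% of 136387 failed candidates (odds ratio 7.37, Fisher's exact p = 1.52e-129). Promoter summits lay at a median of −117 bp from the TSS (interquartile range −195 to −46), and 83.5% were upstream. Summits of failed promoter candidates lay at a median of 91 bp, with 39.4% upstream (odds ratio 7.77, Fisher's exact p = 1.39e-64, a comparison chosen after the data were seen). Coding exons held 7 peaks, 1.07% against 20.5% of failed candidates (adjusted p = 7.66e-53, Fisher's exact test). Their share was 2.17% in the pooled list and 9.67% at an IDR of 0.05, where the exact test still passed (adjusted p = 7.69e-29). By the same exact test, introns held 31.7% against 37.1% (adjusted p = 0.00550), intergenic sequence 10.1% against 24.0% (adjusted p = 5.46e-19), and 3′ UTRs 0.613% against 2.65% (adjusted p = 0.000545). The 3′ UTR share did not pass in replicate 1's list alone (1.18%, exact test, adjusted p = 0.0539) or at an IDR of 0.001 (0.680%, adjusted p = 0.271). The 5′ UTR outside promoters (0.459% against 0.957%, adjusted p = 0.306) and non-coding RNA exons (1.38% against 0.771%, adjusted p = 0.126) did not pass the exact test. Promoter peaks had a median signal of 95.3 (interquartile range 75.2 to 136.0) and other peaks 87.6 (71.2 to 121.1; permutation p = 0.0179). With promoters taken as 200 bp the difference did not pass the test (permutation p = 0.0764).

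**Figure D2:**
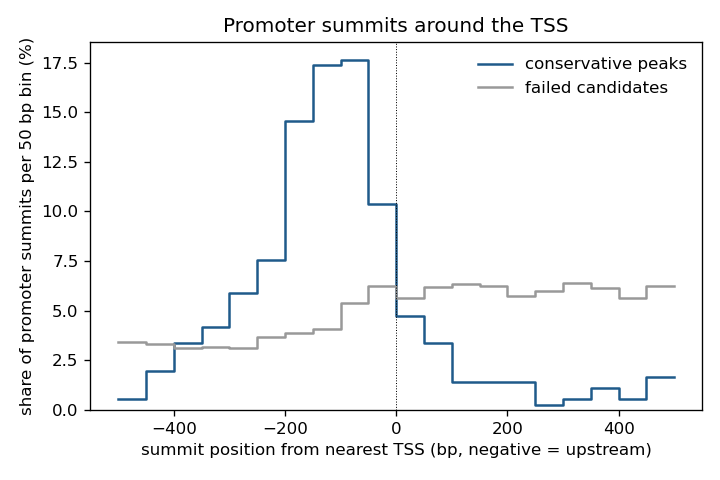
Share of promoter summits (%) in 50 bp bins of position from the nearest TSS (bp, negative is upstream), for 357 conservative peaks (blue) and 19178 failed candidates (grey). The blue line peaks upstream of the TSS, with a median of −117 bp, while the grey line is higher downstream.

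Bound genes were often arranged head to head. Of 442 protein-coding genes with a conservative summit within 500 bp of a TSS, 274 (62.0%) had a TSS facing that of another gene within 1000 bp. Among 10076 unbound genes with a failed candidate the share was 35.8% (odds ratio 2.93, Fisher's exact p = 9.76e-28). Pairs among the strongest sites included CenG1A with mRpS23 and Art3 with mRpS10. A peak between facing genes counts for both of them, so these genes are not independent.

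No chromosome arm passed the adjusted test. The X held 21.3% of conservative peaks against 17.9% of failed candidates (Fisher's exact, adjusted p = 0.102), and 3R held 21.7% against 25.4% (adjusted p = 0.102). Both passed the exact test in replicate 2's list alone (adjusted p = 0.00171 for X and 0.00739 for 3R) and in the pooled list (0.0182 and 0.0214). 2L held 17.5%, 2R 18.7% and 3L 20.8%, and the fourth chromosome held 0 of 653 peaks against 102 failed candidates.

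Of the 23 gene lists with any candidate, 3 passed the adjusted test in the conservative list, and none of the 3 passed in both replicates' own lists. Ribosomal protein genes were bound most often: 20 of 68 members with a candidate (29.4%) had a conservative peak, against 4.04% of other genes (odds ratio 9.90, Fisher's exact, adjusted p = 5.60e-11). In replicate 1's list alone the share was 14.6% (adjusted p = 5.94e-05), and in replicate 2's list alone 3 of 56 members were bound, 5.36% against 4.16% of other genes (adjusted p = 1, exact test). RpS27 (signal 146.1), RpL34b (135.5), RpL7 (128.5) and RpL41 (113.1) had the strongest peaks, ranked 120, 146, 163 and 218 among the 653 main-arm conservative peaks. At an IDR of 0.001 the call ended (2.94%, exact test, adjusted p = 0.732). Of the 20 peaks, 11 overlapped a thresholded peak of replicate 1 and 3 one of replicate 2. Those 3, at RpL34b, RpS4 and RpL23, were among the 11. The rest of the 20 overlapped a thresholded peak of neither replicate.

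Mitochondrial ribosomal protein genes had fewer peaks: 7 of 53 (13.2%) against 4.16% (odds ratio 3.51, Fisher's exact, adjusted p = 0.0489). They were led by mRpL41 (541.2), mRpS23 (367.9), mRpS10 (365.1) and mRpL23 (246.0). The share was 19.4% in replicate 2's list alone (exact test, adjusted p = 0.0144) and 7.02% in replicate 1's (adjusted p = 0.280). The call also ended with the pooled list (exact test, adjusted p = 0.157), with either other TSS distance (0.137 and 0.168), at an IDR of 0.001 or 0.05 (0.0793 and 0.152) and against all protein-coding genes (0.0660). Without the 65 strongest peaks the share was 5.66% (exact test, adjusted p = 0.976). Chemoreceptor genes, receptors of smell and taste, had 0 of 137 (which allows up to 2.19%, for counting error only) against 4.26% (exact test, adjusted p = 0.0489). The exact test did not pass in either replicate's list alone (0.131 without replicate 1 and 0.280 without replicate 2), nor at an IDR of 0.001 (1), a TSS distance of 200 bp (0.364), against all protein-coding genes (0.0660) or without the 65 strongest peaks (0.118).

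The other lists did not pass the exact test in the conservative list. Translation initiation factors had 3 of 32 members bound (eIF6, eIF4EHP and eIF1, exact test, adjusted p = 0.570). Aminoacyl-tRNA synthetases had 2 of 26 (IleRS and GluProRS), oxidative phosphorylation 2 of 62 (ND-ASHI and ND-MWFE), and RNA polymerase II and general transcription 1 of 45 (Polr2B). Insulator and promoter zinc finger factors had 2 of 15 (Chro and Cp190), Polycomb and Trithorax genes 2 of 18 (ph-p and brm), and germ line genes 2 of 12 (bgcn and orb). In replicate 2's list alone Polycomb and Trithorax genes passed (4 of 14, 28.6%, exact test, adjusted p = 0.0255), and in replicate 1's they did not (10.5%, adjusted p = 0.280). Neural genes (elav), muscle genes (tin) and heat shock proteins (Hsp27) had 1 each. The proteasome, spliceosome, DNA replication, cell cycle, casein kinase II, Hox, segmentation, dorsoventral, Enhancer of split and ecdysone lists had 0. No histone gene had a candidate, so that list was not tested.

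**Figure D3:**
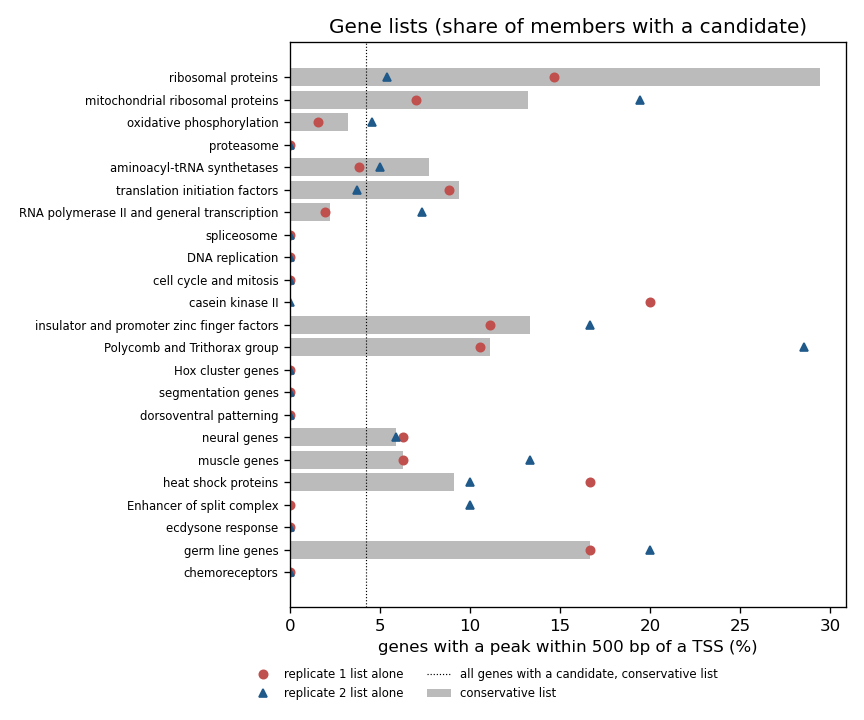
Percent of each list's members with a candidate that had a peak within 500 bp of a TSS, in the conservative list (bars), replicate 1's list alone (circles) and replicate 2's list alone (triangles). Ribosomal proteins were at 29.4, 14.6 and 5.36%; the dotted line marks all genes in the conservative list (4.20%).

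Sequence at the peaks was A/T-rich and held promoter elements. The median GC content within 100 bp of the summit was 35.8% (interquartile range 32.3 to 40.8) against 46.8% (41.3 to 52.2) in failed candidates (permutation p = 1e-05, the smallest that the resamples can give). Random positions had a median of 42.3% (35.3 to 48.8), so the contrast with them was smaller (permutation p = 1e-05). Of 16 motifs, 9 passed the adjusted Fisher's exact test, 7 of them more frequent in peaks. The DNA replication-related element, bound by the factor DREF, was in 5.97% of peaks against 1.78% (odds ratio 3.50, exact test, adjusted p = 2.44e-09). With failed candidates matched on GC the contrast was smaller (2.97%, odds ratio 2.07, exact test, adjusted p = 0.00120). The M1BP element was in 1.53% against 0.298% (exact test, adjusted p = 0.000210), and the GAGA element in 4.75% against 2.51% (adjusted p = 0.00385). ZIPIC elements (4.75% against 2.81%), core promoter motif 6 (0.613% against 0.110%) and core promoter motif 7 (6.28% against 4.07%) each had an adjusted p of 0.0143 by the exact test. Motifs 6 and 7 passed in neither replicate's list alone (0.194 and 0.100 without replicate 1, 0.147 and 0.0680 without replicate 2), and motif 6 did not pass against failed candidates matched on GC (0.394). Without replicate 1, ZIPIC (exact test, adjusted p = 0.208) and M1BP (0.753% of peaks, 0.154) did not pass. M1BP also missed at an IDR of 0.001 (0.193), and ZIPIC with windows of 50 and 250 bp (0.111 and 0.0558, exact test). Among promoter peaks alone the GAGA element did not pass (4.76% against 3.40%, exact test, adjusted p = 0.266). The TATA box was in 8.27% against 4.51% (exact test, adjusted p = 0.000210), but with failed candidates matched on GC its direction turned (adjusted p = 0.552). The full ecdysone response element was not searched, only the partial word AGGTCA from it. That word (3.06% against 5.62%, exact test, adjusted p = 0.0114) and the Zelda element (0.306% against 1.27%, adjusted p = 0.0372) were less frequent in peaks. Neither passed in either replicate's list alone or with failed candidates matched on GC (exact test, adjusted p = 0.183 and 0.339). The Zelda element passed under no alternative run, and its share was 0.565% without replicate 1 and 0.708% without replicate 2. The word AGGTCA also missed at an IDR of 0.001 or 0.05 (exact test, adjusted p = 0.532 and 0.118) and within 50 bp (0.494). Within 50 bp of the summit the GAGA element did not pass (0.613% against 1.27%, exact test, adjusted p = 0.234). The Initiator, Su(Hw), CTCF, PHO, both E-box and heat shock elements did not pass, but 4 of them passed the exact test in other settings. CTCF was in 1.07% of peaks against 0.640% (adjusted p = 0.257), and passed against failed candidates matched on GC (0.306%, exact test, adjusted p = 0.0386) and random positions (0.0479). It also passed in the pooled list (0.0178), at an IDR of 0.05 (0.00762) and within 250 bp (0.0260). PHO, less frequent in peaks, passed in the pooled list (exact test, adjusted p = 0.0428), at an IDR of 0.05 (0.0105) and within 250 bp (0.000333). Su(Hw) passed in the pooled list (exact test, adjusted p = 0.0178), without replicate 2 (0.0493) and among promoter peaks (0.0319). The CAGCTG E-box passed in opposite directions with the 2 other windows: 3.52% against 5.69% within 50 bp (exact test, adjusted p = 0.0444) and 28.2% against 23.8% within 250 bp (0.0174).

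**Figure D4:**
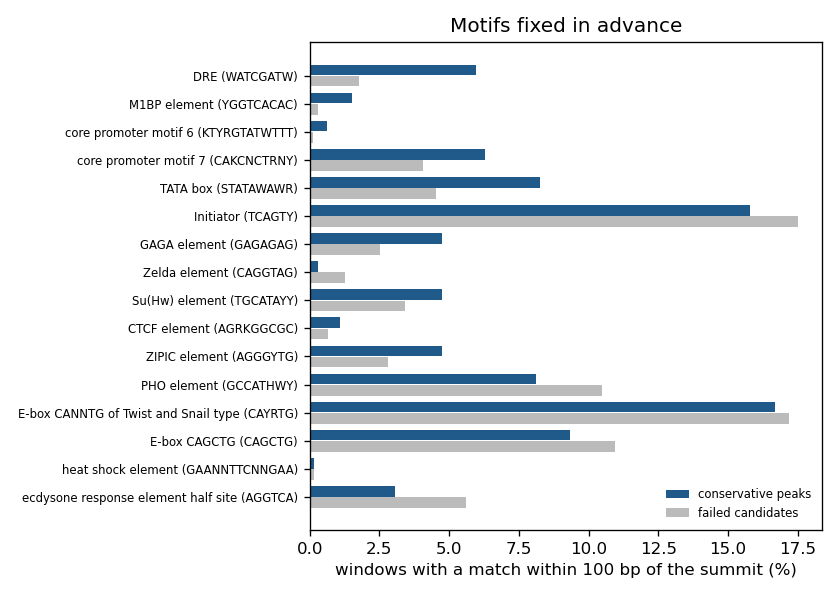
Percent of windows within 100 bp of a summit that held each motif, in 653 conservative peaks (blue) and 136387 failed candidates (grey). The DNA replication-related element (DRE) was in 5.97% of peaks and 1.78% of failed candidates.

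The 7-mer search returned A/T-rich words and words holding CAGTG. Of 8192 7-mers, 376 were over-represented on 2L and 3L, and the 20 best all passed on the other arms. Of these, 18 held only A and T, and the other two were ACAGTGG and CAGTGTA. On the test arms ACAGTGG was in 17.6% of peaks against 2.95% of failed promoter candidates (odds ratio 7.03, Fisher's exact, adjusted p = 4.99e-30), and CAGTGTA was in 8.93% against 1.84% (adjusted p = 2.04e-13). With a background of all failed candidates matched on GC, and so not limited to promoters, 9 of 15 7-mers passed, among them ACAGTGG (17.6% against 1.79%, exact test, adjusted p = 1.01e-30). Only 3 of those 15 held A and T alone: TTTAAAA passed (19.1% against 13.7%, exact test, adjusted p = 0.0141), while AATTTAA (15.4% against 15.2%, adjusted p = 0.942) and AAATTTA (odds ratio 0.995, adjusted p = 1) did not. With failed promoter candidates matched on GC, 9 of 14 passed, ACAGTGG among them (17.6% against 2.21%, exact test, adjusted p = 1.01e-27), and 0 of the 14 held A and T alone.

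The tagged gene itself had a thresholded peak in replicate 1 alone. CkIIalpha-i1 lies at 3L 15816979 to 15818621 on the plus strand. Replicate 1's peak, at 3L 15816922 to 15817004, had its summit at −41 bp from the TSS, a signal of 183.5 and rank 9 of 427. The conservative, pooled and replicate 2 lists had no thresholded peak in the gene or within 500 bp of it. Replicate 2 had no candidate at all between 15801102 and 15828690. Apart from its peak, replicate 1 had none between 15802150 and 15817413 either, so much of that stretch was empty in both. CkIIalpha, CkIIbeta, CkIIbeta2, Ssl and CkIIalpha-i3 had no thresholded peak in any of the 4 lists.

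**Figure D5:**
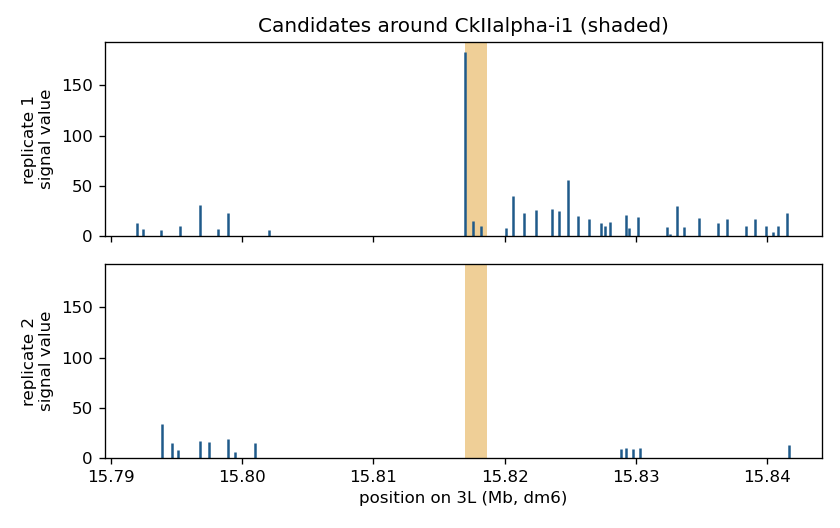
Candidates within 25 kb of the CkIIalpha-i1 peak on 3L (x axis, Mb, dm6), as lines at their summits with the authors' signal value as height, for replicate 1 (top) and replicate 2 (bottom). The shaded band is the gene; replicate 1 reached 183.5 at its start, and replicate 2 had no candidate there.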

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

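Both flagged results concern peaks that the tests of location, genes and sequence took neither as peaks nor as failed candidates. They were part of the correlations between the replicates' signal values. Left-out peaks on the main arms also counted as candidates when genes with a candidate were chosen for the gene lists. Both listings were chosen only after the files were seen. The conservative list's ranked list held 43 peaks past a global IDR of 0.01 that the thresholded list did not hold, 28 of them on the main arms. Among them was the second strongest of the 706 peaks past that threshold, at 2L 480992 to 481192, with a signal of 559.9 and 1416 bp from the nearest TSS, of cbt. The next were near Lk6 (3R 11760962 to 11761129, 386.9) and larp (3R 28326587 to 28326657, 221.5). The file records name a further input file for the thresholded lists, whose role they do not state; its effect was not tested.

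A further 10 conservative peaks lay on contigs outside the main arms, all of them unplaced contigs of the X chromosome. The strongest of these had a signal of 436.0 and rank 7 among the 663 peaks. The replicates' own thresholded lists were uneven here, with 3 of 427 peaks on such contigs in replicate 1 and 38 of 569 in replicate 2. No explanation was tested for the contig peaks.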

How the results depend on the processing

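The IDR thresholds of 0.001 and 0.05, both GC-matched 7-mer searches, the gene lists without the 65 strongest peaks, and other peak lists for the peak count and the tagged gene were chosen after seeing the data. The promoter share, the share of head-to-head genes and the low GC content kept their direction and their side of the threshold under every alternative run. The planned stricter IDR of 0.01 equalled the authors' threshold (663 of 663 peaks passed it), so it moved nothing and has no value of its own. A promoter share among promoter peaks only has no value either. No paired analysis was possible because there was only 1 group.

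Leaving out a replicate (using the other's list alone) gave 427 to 569 peaks, a promoter share of 54.2 to 57.1%, 56.9 to 62.8% head-to-head genes, a median GC of 35.8 to 37.3%, 4 to 5 annotation classes, 0 to 2 arms, 1 to 2 gene lists, 3 to 6 motifs, and 0 to 1 peaks at the tagged gene. At an IDR of 0.001 the conservative list held 150 peaks, 0 gene lists and 5 motifs passed, and 121 replicate 1 peaks were shared. At 0.05 it held 1549 peaks. The pooled list called 2 arms. A TSS distance of 200 bp, all protein-coding genes as background, and leaving out the 65 strongest peaks each left 1 gene list, and a TSS distance of 200 bp left a promoter-signal difference of 5.56 (permutation p = 0.0764). A motif window of 50 bp called 5 motifs, with GAGA at 0.613% and not passing; the GC-matched background turned the TATA box, at 8.27% of peaks. Matched on GC, all failed candidates called 9 7-mers and failed promoter candidates 9. Spearman's rho was 0.540 over thresholded peaks. The cause was not tested. Single classes, lists and motifs kept their call in 89 cases and lost it in 51, and in 2 more the direction turned and the call was lost. Unknown read depth and 2 replicates limit all of these.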

Other observations

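The tests of replicate balance at ribosomal genes (3 versions), of other transcribed lists and of the tagged locus, and the motif positions, were chosen after the results were seen; the 2 tests of GC content were written beforehand. Over all conservative peaks, 33.6% of 119 ACAGTGG matches within 100 bp of a summit were within 50 bp of it, against 52.4% in failed candidates, a difference that was not tested. The word CAGTGTA was in 15.2% of peaks outside promoters and 6.44% of promoter peaks (odds ratio 0.384, Fisher's exact, adjusted p = 0.000388 over the 20 comparisons of this family), while CTACGCC was in 2.36% and 6.16% (adjusted p = 0.0253). CAGTG itself was in 61.1% and 50.4% (exact test, adjusted p = 0.00894). ACAGTGG (17.9% and 14.8%, exact test, adjusted p = 0.355) and CACAGTG (14.2% and 13.4%, adjusted p = 0.820) did not pass. The GAGA element was in 19.4% of peaks within 250 bp of the summit against 5.92% of failed candidates (exact test, adjusted p = 9.98e-31), but did not pass within 50 bp. In the pooled list, insulator and promoter zinc finger factors (5 of 17) and Polycomb and Trithorax genes (5 of 16) also passed, each with an adjusted p of 0.00822 (Fisher's exact test). In replicate 2's list alone only the second of these passed (4 of 14, exact test, adjusted p = 0.0255), and in replicate 1's neither did (0.280 for both).

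Ribosomal protein genes were bound more often in the conservative list. Strong and broad transcription cannot be told apart from other causes. Genes of 7 lists of general cell machinery together were bound in 5.42% of 277 cases (95% Wilson interval 3.31 to 8.74), against 19.9 to 41.1% for ribosomal genes. Other genes were bound in 4.0% of cases, and the 7 lists did not pass against them (Fisher's exact p = 0.217), so the excess expected under this explanation was not seen. The upper bounds of 3 of the 7 lists reached into that range, the highest being 24.8% for mitochondrial ribosomal proteins. These shares were known when the lists were pooled, and no expression data were used. A library difference may contribute. It was examined in 3 versions of 1 test on the log2 ratio of replicate 2 to replicate 1 signal. The first had a median of −0.36 at the 20 ribosomal peaks and 0.16 at 337 other promoter peaks (permutation p = 0.000560). Its outcome was practically known from the replicates' lists, so it decides nothing. The other 2 used failed candidates, where 19083 at other promoters had a median of −0.19. The second had −0.70 at 95 candidates at ribosomal genes (permutation p = 0.000240). The third kept the 85 at genes without a conservative peak and had −0.76 (permutation p = 2.00e-05). There were only 48 such genes, so some candidates shared a gene. All failed candidates had missed the threshold on how well ranks repeat between the replicates. A ribosomal promoter strong in both replicates could thus leave these sets, while a promoter strong in replicate 1 alone could stay. The direction was also visible beforehand, with 12 of 82 members bound in replicate 1's list and 3 of 56 in replicate 2's. These versions are therefore not independent support for a library difference. The permutations treated candidates as independent, and each replicate is 1 library. A ratio between replicates does not explain why these genes passed in the conservative list. What differs between the libraries stays open, and no biological explanation was tested.

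Peaks had a low GC content. Libraries that favour low-GC fragments are argued against, since signal rose with GC across failed candidates in both replicates (rho = 0.146 and 0.117). Soft-masked repeats are argued against as the whole cause, since peaks with no masked base still had a median GC of 42.0% against 50.7% (permutation p = 1e-05, the smallest possible). But only 98 of 653 peaks had no masked base, against 51770 of 136387 failed candidates (37.96%). The comparison therefore covers a small part of the peaks, and masked sequence may still contribute to the low GC content of the rest. A GC bias of the control library stays open, and no biological explanation was tested.

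The peak at the tagged gene was in replicate 1 alone. A general lack of replicate 2 candidates around replicate 1 peaks was not seen. Only 5 of 423 other replicate 1 peaks (1.18%) had none within 10 kb. But 381 of 427 replicate 1 peaks overlapped a replicate 2 candidate, so for them one within 10 kb was given beforehand. The share therefore does not decide the question for peaks, like this one, without such an overlap. Extra copies of the locus in replicate 1's immunoprecipitated DNA, absent from its control, cannot be told apart from other causes, since the 2 tests tried went opposite ways. The first counted replicate 1 candidates within 10 kb and found 12, under the median of 22 around its other peaks. Between 15802150 and 15817413 neither replicate had a candidate apart from the peak itself, so part of that window was empty in both. The second, added after that count, set 15 other replicate 1 candidates inside the 27.6 kb without replicate 2 candidates (median signal 17.4) against 72 within 50 kb outside (11.1, permutation p = 0.0262). A mislabelled sample was not tested, although the replicates shared 263 main-arm peaks against at most 6 in random placements. A difference between the controls stays open, since no control was analysed here, and no biological explanation was tested.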
